A study of Rattus norvegicus with 40 samples.

How the data were processed

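RNA was taken from single whole rat retinas and made into stranded mRNA libraries, per the labels' protocols. The submitters' processing notes name HISAT2, edgeR and the rat genome build Rnor_6.0. The authors deposited 1 table of raw counts per gene, with 3 annotation columns and 40 count columns.

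Samples were grouped from their titles, which state room air or OIR, anemic or not, the age and a replicate number, and all 40 samples received a group. Columns of the table were to be given to samples by name. The column names are codes, and none of them pointed to a single sample through its title, description, characteristics or protocols. Of each code, the number with its letter and the index were looked for as words in the description of the series, and neither was found. The number alone and the letter alone were not looked for there. The order of the columns was not used to assign them, because an order is not a label and no source used here states that it follows the samples. The level of any gene was not used either, because that would presume the groups that the comparisons test. All 40 count columns were left unmatched and were not used. The planned quasi-likelihood tests, gene list tests and interaction tests were accordingly not run, and depth per sample is not reported. Per the series description, the OIR groups at postnatal day 20 held 4 males and 4 females each and were also compared within each sex. That comparison was not run for a further reason: no sample label and no readable part of a column code states the sex of a library, and sex was not inferred from expression.

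Names were compared with Python 3.11.15. The rule was the same name as a title or description after removing punctuation and case. The further 4 rules were chosen after the column names had been seen: the name inside a title or description or the reverse, for parts of at least 4 characters, the code as a word in any label, the digits of the code as a word in any label, and the index as a word in any label. The matching code was tested on simulated labels into which the codes had been written, where each of the 5 rules matched 40 of 40 columns. That outcome follows from how the labels were simulated, so it checks only that the code runs as intended and says nothing about the real labels. Gene symbols of the table were matched to the fixed lists exactly as written.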

Results

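Whole retinas of rat pups were profiled by RNA sequencing to ask how anemia brought about by blood removal bears on the retina, with and without oxygen-induced retinopathy (OIR). OIR is an animal model of retinopathy of prematurity. In the rat protocol used here newborn pups breathe oxygen that swings between high and low levels, and pups kept in room air serve as its reference. The 40 samples fell into 8 groups by their titles. At postnatal day 15 there were 4 room air samples, 4 anemic room air samples, 4 OIR samples and 4 anemic OIR samples. At postnatal day 20 there were 4 room air samples, 4 anemic room air samples, 8 OIR samples and 8 anemic OIR samples. Each library was made from a single retina.

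The series description names a comparison of anemic with non-anemic pups in room air and in OIR at each age. The design also implies a comparison of OIR with room air in pups that were not bled. It further allows tests of whether the response to anemia differed between room air and OIR or between the ages. The count table held 32883 gene rows and 40 count columns. The column names were codes made of a number, a letter and an index. By an identical title or description, 0 of the 40 columns matched a single sample. The columns were therefore assigned to no sample and no group. No expression value, fold change or test is reported for any of these comparisons, and whether retinal genes differed between anemic and non-anemic pups was not analysed here.

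The gene lists fixed before the data were examined could be set against the gene symbols of the table, which needed no count column. Of 708 distinct gene symbols over 33 lists, 667 were named in the table. For hypoxia and HIF targets, the genes induced when oxygen is low, 33 of 36 symbols were present. For angiogenic signalling and tip cells, the genes that direct new vessel growth, 32 of 32 were present. For iron homeostasis, 28 of 30 were present. For red blood cells, which include the globin genes, 17 of 25 were present. Presence of a symbol says that the gene was in the annotation used for counting and nothing about its level in any retina. Absence of a symbol does not say that the gene was missing from the annotation. Symbols were matched exactly as written, and some lists, among them those for hypoxia and red blood cells, hold alternative names of a gene.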

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

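The number of count columns matched to a single sample was 0 of 40 by identical name. It was also 0 under each of the 4 other matching rules, which were chosen after the column names had been seen. No paired analysis was possible because no source used here gives a key from the column codes to the replicate numbers and groups of the titles. The titles also do not state that samples with the same replicate number in different groups form a pair. Whether the codes themselves stand for groups and animals is open. The alternatives planned for the gene tests, among them a block for the replicate number, were not run because no column entered a group.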

Other observations

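The digits of each column code were divided, by a rule chosen after the names had been seen, into the last pair of digits and the digits before it, and columns with the same digits before the last pair were taken as a block. Under this rule the codes form 8 blocks. The blocks 1, 2, 3, 4, 5 and 6 hold 4 columns each, and the blocks 9 and 10 hold 8 columns each. These sizes equal those of the 8 groups in the titles, but the equality rests on this rule, and other divisions of the digits were not tried. Neither the codes nor the labels say which block is which group, so no values were compared between blocks.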
